A study of Bos taurus with 31 samples.

How the data were processed

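Liver RNA of 31 female fetuses, collected on day 83 of gestation from separate Angus-cross heifers, was measured by RNA sequencing. Per the labels, libraries were strand-specific and were read in pairs of 150 bp. The submitters' processing notes name CASAVA, FastQC version 0.11.8, MultiQC version 1.9, STAR version 2.7.3a and edgeR, without their roles or order. The genome build, the annotation release, the program that counted reads per gene and the use of strand in that counting are not given in the sources used here.

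The deposited table holds raw counts per gene, whole numbers that had not been normalized, for 27607 Ensembl bovine gene identifiers. Of these, 5686 had 0 counts in all 31 libraries. Each column was matched to its sample by title, and the groups were taken from the treatment label. The replicate numbers used here follow the order of the samples within a group and are names only, so they pair nothing across groups. Total counts ranged from 13062894 to 18458776 per library. No sequencing batch or breeding group is given per sample in the labels, so none could be entered in a model. No 2 libraries matched within sampling noise: over the 465 pairs, the chi-square statistic per degree of freedom was at least 6.6, for genes with 10 or more counts in the pair. The p-values measure the spread between fetuses of separate heifers that shared a sire.

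The files do not pair the gene identifiers with names. The reference gene table that was supplied lists 37063 genes and held no Ensembl identifier, so 0 identifiers were matched to a symbol. For this reason 64 gene lists chosen before the data were examined, their tests and scores, and a planned covariate of erythroid genes could not be run. Genes are therefore given by identifier, with no statement on their function, position, paralogs or overlapping neighbours. Any sharing of reads with a similar copy could not be checked.

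The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 4 groups, with its minimum count of 10 and minimum total of 15, which left 14228 genes. Libraries were scaled by TMM, and all 31 were fitted together with 1 mean per group. The tests comprised 6 pairwise contrasts, the effect of supplementation averaged over gain, the effect of gain averaged over supplementation, and their interaction. Supplementation means VTM against NoVTM throughout. P-values were adjusted within each contrast by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors were derived from the fitted log2 fold change and its F statistic, and 95% intervals from the degrees of freedom of the test. CPM values are counts scaled to the TMM-adjusted library size in the usual CPM unit, given as mean ± SD. Principal components were computed from log2 CPM with a prior count of 2.

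The rule for named genes, set before the data were examined, asked for genes past the threshold that had a symbol and a mean of at least 1 CPM in the higher group, or the 5 with the smallest p where none passed. As no symbols were at hand, the symbol condition was dropped after the data were seen. Genes were then taken as the 2 with the smallest p in each direction per contrast that reached 1 CPM in at least 1 group mean. ENSBTAG00000013657, which did not reach 1 CPM, falls outside this rule and was chosen after its values were seen. In the contrast where 3 genes passed, the third is described without its identifier. An identifier named for a comparison where it did not pass is given as not passing.

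The edgeR procedure was tested on simulated data, drawn from the means and library sizes of the real samples, with 50 genes changed at each of 4 fold sizes. For the effect of gain, 54% of genes changed by 1.25-fold, 82% of those changed by 1.5-fold and 94% of those changed by 2-fold were recovered among 14130 genes tested. For VTM_LG against NoVTM_LG the shares were 36%, 68% and 90% among 14143 genes. For the interaction they were 2%, 38% and 68% among 14147 genes. Of the calls, 1.81% were false for gain, 6.37% for VTM_LG against NoVTM_LG, 7.51% for supplementation, 5.41% for VTM_MG against VTM_LG and 3.96% for the interaction. Each gene was drawn on its own, so the simulated data held no variation shared between genes and no outlying libraries. The simulated contrasts gave 101 to 173 calls, and the adjustment is less strict where many genes change. The shares recovered may therefore be too high for the real contrasts.

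Other settings chosen before the data were examined were scaling by relative log expression, no filter on low counts, a filter of more than 1 CPM in 7 libraries, the Wald test of DESeq2 1.42.0, voom with quality weights in limma 3.58.1, a fit of the compared groups alone, an adjusted p of 0.10, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Further settings were chosen after seeing the data: leaving out 2 VTM_LG libraries together, a robust edgeR fit, the edgeR likelihood ratio test, and the first principal component as a covariate. Measures of library quality were compared between groups by exact two-sided permutation tests of the mean in scipy 1.17.1, with adjustment over 48 tests.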

Results

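Gene expression was measured in the liver of 31 bovine fetuses on day 83 of gestation. All were female, and their dams were Angus-cross heifers bred to a single sire. The dams followed a factorial design. VTM dams received 0.45 kg per day of a corn carrier with a vitamin and mineral premix, begun 71 to 148 days before breeding, and NoVTM dams did not. From breeding, LG dams were fed for a low body weight gain of 0.28 kg per day, and MG dams received an energy and protein supplement for a moderate gain of 0.79 kg per day. There were 8 fetuses in NoVTM_LG, 8 in VTM_LG, 8 in NoVTM_MG and 7 in VTM_MG. Below, supplementation means VTM only, and the energy and protein supplement belongs to the MG level of gain. The comparisons addressed whether maternal supplementation, maternal gain or their combination altered the fetal liver transcriptome.

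The libraries held 14746449 ± 1104678 counts (SD, n = 31), with a range of 13062894 to 18458776. Of 27607 genes in the table, 14228 had enough counts to be tested. The biological coefficient of variation between fetuses of a group was 15.6%, a single value pooled over all tested genes. The gene most abundant over all libraries took 10.12% ± 1.21 of the counts (SD, n = 31). The 10 genes most abundant over all libraries together took 32.76% ± 1.62. The groups did not separate along the first principal components, which carried 14.1% and 7.9% of the variance. None of 48 exact permutation tests of library measures between groups gave a p under 0.05, and the smallest adjusted p was 0.671. The smallest unadjusted p of these tests was 0.0622, for the first component in VTM_MG against VTM_LG. The tests compare means and not spread. On the first component the SD was 26.3 in VTM_LG, against 4.15 to 7.02 in the other groups.

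**Figure D1:**
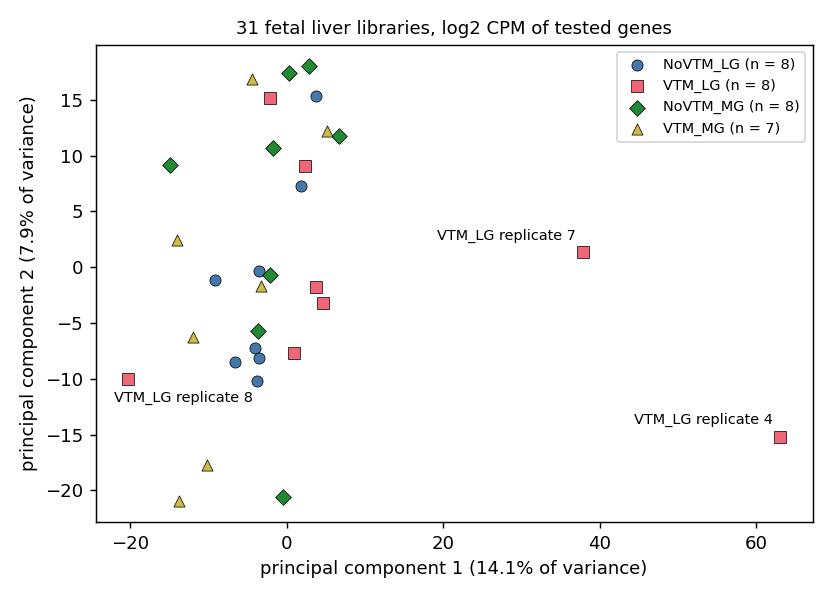
Position of the 31 fetal liver libraries on the first and second principal components of log2 CPM, which carry 14.1% and 7.9% of the variance. Each point is 1 fetus, marked by group. VTM_LG replicates 4 and 7 lie at 63 and 37.9 on the first component, and VTM_LG replicate 8 lies at -20.2.

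Within VTM_LG, 2 libraries stood apart from the rest. VTM_LG replicate 4 lay at 63 on the first component and VTM_LG replicate 7 at 37.9, while the other 29 lay between -20.2 and 6.69. In VTM_LG replicate 4, 1008 genes were at least 2-fold below their median over all libraries and 200 were at least 2-fold above it. For VTM_LG replicate 7 these counts were 561 and 107. In the other 29 libraries 90 to 206 genes were as far below and 39 to 143 as far above, so the 107 was within their range. The total counts of replicates 4 and 7, 13576508 and 16360774, were also within the range of the other libraries.

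Maternal gain, averaged over supplementation, was the only one of the 9 contrasts with genes past the threshold in the main test. In edgeR, 3 genes fell in MG fetuses and 0 rose. ENSBTAG00000012855 averaged 33.7 ± 8.4 CPM in LG (SD, n = 16) and 22.1 ± 4.04 CPM in MG (SD, n = 15), a log2 fold change of -0.60 (SE 0.102, adjusted p = 0.0205). ENSBTAG00000055207 averaged 361 ± 47.8 CPM in LG and 277 ± 41.6 CPM in MG, a log2 fold change of -0.38 (SE 0.0681, adjusted p = 0.0207). Each of them was below the LG median in 15 of 15 MG fetuses. The third gene averaged 6.99 ± 2.53 CPM in LG and 3.29 ± 1.56 CPM in MG, a log2 fold change of -1.08 (SE 0.199, adjusted p = 0.0239), and was below the LG median in 14 of 15 MG fetuses.

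Among genes with higher values in MG that reached 1 CPM in a group mean, ENSBTAG00000016359 had the smallest edgeR p in the gain contrast. It averaged 1.69 ± 0.386 CPM in LG and 2.44 ± 0.586 CPM in MG and did not pass in edgeR (log2 fold change 0.53, SE 0.13, adjusted p = 0.285). The smallest p of all genes with higher values belonged to ENSBTAG00000013657, at 0.45 ± 0.175 CPM in LG and 0.818 ± 0.277 CPM in MG (log2 fold change 0.87, SE 0.2, adjusted p = 0.203 in edgeR). It passed only in the edgeR likelihood ratio test (adjusted p = 0.0351), which called 11 genes, 10 lower and 1 higher. At an unadjusted p under 0.05, 1113 genes were found, and 706 were found without VTM_LG replicates 4 and 7. With no change, 5% of the tested genes, or 711.4, would be found on average. Other splits of the libraries by gain had a median of 561. The count of genes past the threshold was 9 in DESeq2 and 5 in limma voom, all lower in MG and including the 3 genes in each case. It fell to 0 without VTM_MG replicate 2, to 1 without VTM_LG replicate 2, NoVTM_MG replicate 7, NoVTM_MG replicate 8 or VTM_MG replicate 7, and rose to 7 without NoVTM_LG replicate 3 and to 6 without NoVTM_LG replicate 6. It was 5 without NoVTM_LG replicate 7, VTM_LG replicate 8, NoVTM_MG replicate 2 or VTM_MG replicate 1. The fold changes moved little where calls were lost. Without VTM_MG replicate 2, the log2 fold changes of the 3 genes were -0.58, -0.36 and -1.02, each with an adjusted p of 0.0559 in edgeR. Without each of the other 4 libraries that left 1 gene, ENSBTAG00000055207 stood between -0.38 and -0.36 and the third gene between -1.06 and -0.99, with adjusted p-values of 0.0502 to 0.0673. Over the 40 other settings, ENSBTAG00000012855 passed in 39, ENSBTAG00000055207 in 35 and the third gene in 31. Their highest adjusted p-values were 0.0559, 0.0579 and 0.0673.

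The effect of gain on the 3 genes was not shown to depend on supplementation. In edgeR the adjusted p of the interaction was 0.542 for ENSBTAG00000012855, 0.533 for ENSBTAG00000055207 and 0.993 for the third gene. The unadjusted edgeR p-values were 0.0996, 0.091 and 0.976. Without supplementation the log2 fold changes for gain were -0.77, -0.50 and -1.09, and with it -0.43, -0.26 and -1.08. A smaller effect with supplementation is therefore not excluded for the 2 named genes. ENSBTAG00000012855 averaged 37.2 ± 9.32 CPM in NoVTM_LG (SD, n = 8), 30.2 ± 6.06 in VTM_LG (n = 8), 21.8 ± 4.33 in NoVTM_MG (n = 8) and 22.5 ± 3.98 in VTM_MG (n = 7). ENSBTAG00000055207 averaged 368 ± 65.3, 355 ± 23.2, 260 ± 37.3 and 295 ± 40.4 CPM in the same groups.

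**Figure D2:**
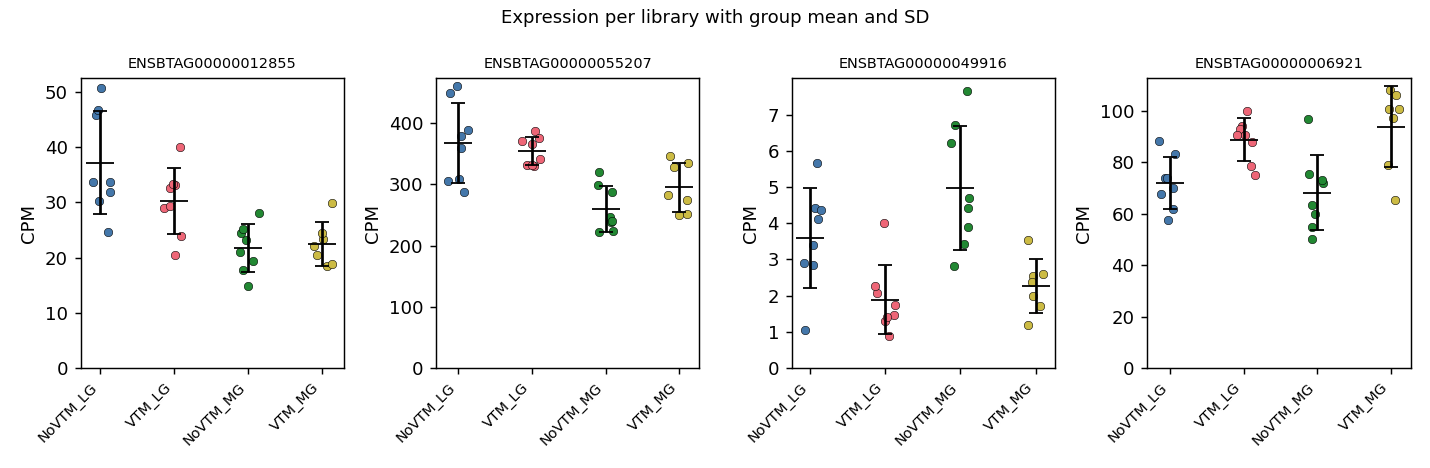
CPM of 4 genes in each of the 31 libraries, by group. Points are fetuses, and the horizontal and vertical bars are the group mean and SD. ENSBTAG00000012855 and ENSBTAG00000055207 are lower in both MG groups than in both LG groups. ENSBTAG00000049916 averages 4.29 CPM without and 2.07 CPM with supplementation, and ENSBTAG00000006921 averages 70.1 and 91 CPM. Neither passed in the edgeR quasi-likelihood test, and both passed in DESeq2 and limma voom.

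Supplementation, averaged over gain, gave 0 genes past the threshold in edgeR, with 412 genes at an unadjusted p under 0.05 (623 without NoVTM_MG replicate 6) against 711.4 with no change. ENSBTAG00000049916 came nearest. It averaged 4.29 ± 1.66 CPM in NoVTM (SD, n = 16) and 2.07 ± 0.858 CPM in VTM (SD, n = 15), and was below the NoVTM median in 15 of 15 VTM fetuses (edgeR log2 fold change -1.03, SE 0.195, adjusted p = 0.106). ENSBTAG00000043250 averaged 5.08 ± 2.24 and 2.62 ± 1.31 CPM in the same order (edgeR log2 fold change -0.98, SE 0.212, adjusted p = 0.263). Higher values in VTM were measured for ENSBTAG00000006921, at 70.1 ± 12.3 CPM in NoVTM and 91 ± 12.2 CPM in VTM (edgeR log2 fold change 0.38, SE 0.0783, adjusted p = 0.189). They were also measured for ENSBTAG00000000460, at 4.58 ± 0.948 and 6.16 ± 0.988 CPM, which was above the NoVTM median in 15 of 15 VTM fetuses (edgeR log2 fold change 0.43, SE 0.0967, adjusted p = 0.34). DESeq2 called 3 genes and limma voom 2. ENSBTAG00000049916 and ENSBTAG00000006921 were among them in both tools, with an adjusted p of 0.00136 and 0.0122 in DESeq2 and of 0.0232 each in limma voom. Over the 40 other settings the adjusted p ranged from 0.00136 to 0.283 for ENSBTAG00000049916 and from 0.0122 to 0.506 for ENSBTAG00000006921, which passed in 8 and 5 of them. ENSBTAG00000043250 was the other DESeq2 call (adjusted p = 0.0122). It passed in 4 of the 40, the others being the edgeR likelihood ratio test and the fits without NoVTM_LG replicate 4 or VTM_MG replicate 2, with an adjusted p of up to 0.643. ENSBTAG00000000460 passed in 0 of the 40, with an adjusted p of at least 0.0551. With no filter on low counts, 924 of 21921 genes had an unadjusted p under 0.05. The edgeR count was 1 without VTM_LG replicate 4, 2 without NoVTM_LG replicate 4 or NoVTM_MG replicate 3, and 3 without VTM_MG replicate 2.

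Gain without supplementation was compared between NoVTM_MG and NoVTM_LG. The genes nearest the threshold were those of the averaged contrast. ENSBTAG00000012855 had a log2 fold change of -0.77 (SE 0.142) and ENSBTAG00000055207 one of -0.50 (SE 0.0946), each with an adjusted p of 0.0541 in edgeR, so 0 genes passed. At an unadjusted p under 0.05 there were 653 genes, against 1327 in limma voom and 1134 of 21921 genes with no filter on low counts. DESeq2 called 9 genes and limma voom 2, all lower in NoVTM_MG and both named genes included (adjusted p 0.0012 and 0.00169 in DESeq2, 0.0106 each in limma voom). Leaving out 1 library moved the edgeR count to 7 without NoVTM_LG replicate 3, to 5 without NoVTM_LG replicate 6 and to 3 without VTM_MG replicate 1. It was 2 without NoVTM_LG replicate 7, VTM_MG replicate 2 or VTM_MG replicate 5, and 1 without VTM_LG replicate 3, VTM_LG replicate 4, NoVTM_MG replicate 6 or NoVTM_MG replicate 8.

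Gain with supplementation was compared between VTM_MG and VTM_LG. ENSBTAG00000047293 averaged 11.9 ± 0.728 CPM in VTM_MG (SD, n = 7) and 7.74 ± 2.12 CPM in VTM_LG (SD, n = 8), and did not pass in edgeR (log2 fold change 0.61, SE 0.128, adjusted p = 0.246). ENSBTAG00000008014 averaged 31.8 ± 3.16 and 40.3 ± 6.26 CPM in the same order (edgeR log2 fold change -0.34, SE 0.0733, adjusted p = 0.246). In edgeR 0 genes passed, while 2106 had an unadjusted p under 0.05, the most of any contrast. Without VTM_LG replicate 4 there were 1196, and without VTM_LG replicates 4 and 7 there were 782, with 0 genes passed in each case. There were 1274 with only these groups in the fit and 665 with the first principal component as a covariate. DESeq2 called 1 gene and limma voom 0. Without VTM_LG replicate 8, which lay opposite to those libraries on the first component, 23 genes passed, 19 higher and 4 lower in VTM_MG. ENSBTAG00000047293 was the DESeq2 call (adjusted p = 0.018), and it also passed in the edgeR likelihood ratio test (adjusted p = 0.0263). Both named genes were among the 23, each with an adjusted p of 0.0474 in edgeR.

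Supplementation at low gain was compared between VTM_LG and NoVTM_LG. ENSBTAG00000020963 averaged 50.5 ± 4.68 CPM in VTM_LG (SD, n = 8) and 43.1 ± 2.87 CPM in NoVTM_LG (SD, n = 8), and did not pass in edgeR (log2 fold change 0.23, SE 0.0558, adjusted p = 0.601). ENSBTAG00000043250 averaged 2 ± 0.42 and 4.68 ± 2.51 CPM in the same order (edgeR log2 fold change -1.23, SE 0.302, adjusted p = 0.601). The value of ENSBTAG00000011803 in VTM_LG, 3.42 ± 6.86 CPM against 0.638 ± 0.21 in NoVTM_LG, rested on 20.3 CPM in VTM_LG replicate 1. Its log2 fold change was 2.40 with that library and 0.64 without it, and it did not pass in either case. In edgeR 0 genes passed and 1174 had an unadjusted p under 0.05, which became 533 without VTM_LG replicates 4 and 7, 614 without VTM_LG replicate 4 alone and 1907 without VTM_LG replicate 8. It was 768 with only these groups in the fit and 544 with the first principal component as a covariate. DESeq2 and limma voom each called 0.

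Supplementation at moderate gain was compared between VTM_MG and NoVTM_MG. ENSBTAG00000006921 averaged 93.7 ± 15.8 CPM in VTM_MG (SD, n = 7) and 68.2 ± 14.6 CPM in NoVTM_MG (SD, n = 8), and did not pass in edgeR (log2 fold change 0.46, SE 0.112, adjusted p = 0.955). ENSBTAG00000049916 averaged 2.28 ± 0.746 and 4.98 ± 1.71 CPM in the same order (edgeR log2 fold change -1.13, SE 0.277, adjusted p = 0.955). ENSBTAG00000047664 averaged 19.2 ± 3.3 and 25.6 ± 3.27 CPM. In edgeR 0 genes passed and 650 had an unadjusted p under 0.05, or 946 without VTM_LG replicates 4 and 7. There were 1160 in limma voom and 1067 of 21921 genes with no filter on low counts. DESeq2 and limma voom each called 0.

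Both factors differed between VTM_MG and NoVTM_LG and between VTM_LG and NoVTM_MG. In VTM_MG against NoVTM_LG, ENSBTAG00000012855 had a log2 fold change of -0.72 (SE 0.148, adjusted p = 0.34 in edgeR), and ENSBTAG00000047175 averaged 12.6 ± 4.01 CPM in VTM_MG (SD, n = 7) and 21.5 ± 3.95 CPM in NoVTM_LG (SD, n = 8). In edgeR 0 genes passed and 405 had an unadjusted p under 0.05, against 722 in limma voom and 845 of 21921 genes with no filter on low counts. DESeq2 called 1 gene, ENSBTAG00000012855 (adjusted p = 0.0188), and limma voom 0. In VTM_LG against NoVTM_MG, ENSBTAG00000055207 had a log2 fold change of 0.45 (SE 0.0946) and ENSBTAG00000049916 one of -1.40 (SE 0.271), each with an adjusted p of 0.137 in edgeR. In that contrast 0 genes passed in edgeR and 1272 had an unadjusted p under 0.05, which became 813 with only these groups in the fit, 789 without VTM_LG replicate 4 and 652 without VTM_LG replicates 4 and 7. DESeq2 called 6 genes, both named ones included (adjusted p 0.0162 and 0.00262), and limma voom 0, and the edgeR count was 1 without VTM_LG replicate 4 and 2 without NoVTM_LG replicate 4.

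The interaction asked whether the effect of supplementation differed between the levels of gain. ENSBTAG00000007728 averaged 69.3 ± 3.35 CPM in NoVTM_LG, 77 ± 8.93 in VTM_LG, 77.2 ± 4.73 in NoVTM_MG and 66.1 ± 4.66 in VTM_MG (edgeR interaction -0.38 on the log2 scale, SE 0.0872, adjusted p = 0.431). ENSBTAG00000006320 averaged 49.9 ± 3.74, 42.5 ± 5.64, 44.9 ± 3.34 and 50.4 ± 3.99 CPM in the same groups (edgeR interaction 0.40, SE 0.0993, adjusted p = 0.431). In edgeR 0 genes passed and 1516 had an unadjusted p under 0.05, which became 920 without VTM_LG replicates 4 and 7 and 598 with the first principal component as a covariate. DESeq2 and limma voom each called 0.

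**Figure D3:**
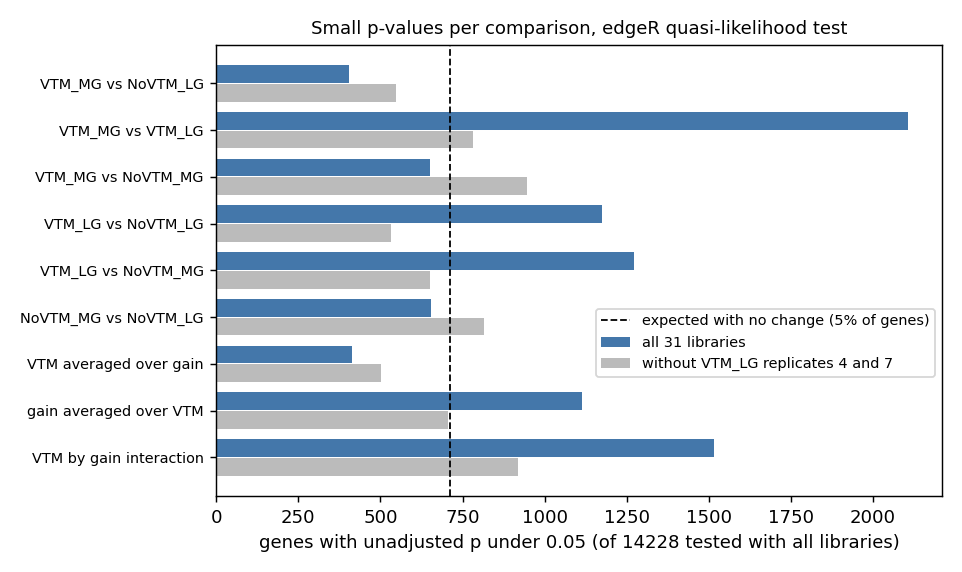
Number of genes with an unadjusted p under 0.05 in each of the 9 contrasts, with all 31 libraries and without VTM_LG replicates 4 and 7. The dashed line marks 711.4 genes, the 5% of tested genes expected on average with no change. The bar of VTM_MG against VTM_LG falls from 2106 to 782.

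The size of change that the data allow was narrow for most genes. The 95% interval of the fold change lay within 2-fold in either direction for 98.8% of genes for supplementation and 98.7% for gain. For the interaction this share was 86%, and for the pairwise contrasts it was between 94.3% and 95.7%. Intervals within 1.5-fold were reached by 91.5% of genes for supplementation, 90.6% for gain and 61.5% for the interaction.

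Fold changes of contrasts that share no library were compared across genes, which are not independent replicates. The correlation between the effect of supplementation at low gain and at moderate gain was -0.0923 over 14228 genes. In mean log2 CPM it was -0.0917, within the range of -0.189 to 0.196 that held the central 95% of 1000 permutations of the group labels. Between the effect of gain without and with supplementation it was -0.00231, and 0.00864 in mean log2 CPM against a permuted range of -0.194 to 0.19. Without VTM_LG replicates 4 and 7 the correlation of fold changes was 0.00153 for supplementation and 0.0154 for gain, over 14225 genes. By the edgeR quasi-likelihood test no adjusted call was shared, as 0 genes passed in these 4 contrasts. DESeq2 called 0 genes in both supplementation contrasts. For gain it called 9 lower genes without supplementation and 1 higher gene with it, so none was shared in the same direction. The genes that passed for gain averaged over supplementation were lower in MG in both gain contrasts, but passed in neither in edgeR. With supplementation, their unadjusted edgeR p-values were 0.00678 for ENSBTAG00000012855, 0.0109 for ENSBTAG00000055207 and 0.000673 for the gene given without its identifier. Without it, they were 4.9e-06, 7.6e-06 and 0.000404 in the same order. These genes were picked on the average of both contrasts, so their recurrence is not an independent test. At an unadjusted p under 0.05, 20 genes were shared in the same direction between the supplementation effects and 28 between the gain effects, where independent lists of those sizes would share 26.5 and 48.4. In opposite directions, for which no number for independent lists was computed, 45 and 41 were shared. Without VTM_LG replicates 4 and 7, the counts in the same direction were 22 and 24, against 17.6 and 22.2 for independent lists, and those in opposite directions were 23 and 21.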

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

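The tests of the excess of small p-values were chosen after that result was seen, except the comparison with other pairs of libraries. For VTM_LG replicate 4, only the correlation with other libraries was. For the 3 gain genes, the fit without the outlying libraries and the ratio of total counts were.

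Of 136 groups of values examined, 11 held a library whose gap to its nearest neighbour was large for the range of its group, where chance gives about 6.8. VTM_LG replicate 4 had 4 of these gaps. The gene with the most counts over all libraries took 5.48% of the counts there, against 8.98% to 11.7% in the rest of the group. The gene ranked second over all libraries took 10.3%, against 5.28% to 6.5%. The order of these genes was thus reversed in VTM_LG replicate 4. The median absolute log2 deviation of its genes from all libraries was 0.336, against 0.12 to 0.213. It also held 4 CPM of ENSBTAG00000049916, against at most 2.261 in the rest of the group.

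The distance of VTM_LG replicate 4 was not confined to a few abundant genes, since 1008 genes were at least 2-fold below their median. Its deviation was 0.335 without the 10 most abundant genes, against at most 0.21 in any other library. That value decides little, as a median over all tested genes hardly moves when 10 are left out. An exchange with another group would not make VTM_LG replicate 4 stand apart. Its smallest distance to the mean of another group was 0.605, while the libraries of those groups lay within 0.403 of their own means. Its deviation correlated across genes with the first principal component of the other 30 libraries (size of r 0.366, rank 2 of 31 libraries treated alike, median 0.0819), so a shared axis such as cell make-up or RNA state may contribute. Without VTM_LG replicate 7 the value was 0.139, so most of that axis is shared with this library, and without gene names its nature stays open. No biological explanation was tested.

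The excess of small p-values in VTM_MG against VTM_LG may come from VTM_LG replicates 4 and 7. Without them 782 genes had an unadjusted p under 0.05, against 2106 with them and 711.4 with no change. The loss of any 2 libraries does not account for this, since the other 27 pairs of VTM_LG libraries left between 1094 and 3247. At the adjusted threshold, removing replicate 8 with replicate 1, 2, 3, 5 or 6 left 171, 59, 385, 57 and 255 genes and removing replicates 1 and 3 left 2, while the other pairs left 0, those of replicate 8 with 4 or 7 included. A response to maternal gain shared by the remaining libraries cannot be told apart from none. With replicates 4 and 7 kept, adjusted calls reached 385. Without them 6 libraries were left, and 782 is slightly above the 711.4 expected on average with no change. In the contrasts without VTM_LG the drawn splits had medians of 380, 436 and 456, so 711.4 may be too high a bar. No splits were drawn without replicates 4 and 7. The other splits call for care too: of 100 splits of these 15 libraries, 12 gave 2106 or more, and the highest of the others gave 2912. The median of the drawn splits was 1301 where these libraries fell in the same group and 502 where they were parted, which points to a structure of the samples.

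For the 3 genes lower in MG, chance was a less likely source of the count in this contrast taken alone: 2 of 100 splits of the libraries by gain within each level of supplementation gave 3 or more genes, the real one included, and the highest of the others gave 5. This was the only contrast of 9 with a call, and 2 of 100 is not adjusted for the 9 contrasts. For genes at an unadjusted p under 0.05 in the same contrast, chance could not be excluded, since 10 of 100 splits gave 1113 or more and the highest of the others gave 2698. Depth hardly differed between the gain levels, as the ratio of total counts, MG over LG, was 1.003 (95% interval 0.950 to 1.060). A difference in depth is thus an unlikely source of the 3 genes. Each gene fell by at least 1.3-fold in counts scaled for depth, so its fold and this ratio are not on the same scale. The 2 outlying libraries do not account for the 3 genes, since 3 of the 3 passed without these. An effect of maternal gain stays a hypothesis, since it was found and tested on the same data and reads shared with similar genes could not be checked. The count was 0 without VTM_MG replicate 2, but the log2 fold changes were then -0.58, -0.36 and -1.02, against -0.60, -0.38 and -1.08 with all libraries.

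In the other 8 contrasts the edgeR count at the adjusted threshold was 0, which any split reaches (100 of 100), so the splits say nothing about chance there. The highest of the others was 0 for VTM_MG against NoVTM_LG, 3 for VTM_MG against VTM_LG, 1 for VTM_MG against NoVTM_MG, 9 for VTM_LG against NoVTM_LG, 4 for VTM_LG against NoVTM_MG, 2 for NoVTM_MG against NoVTM_LG, 1 for supplementation and 6 for the interaction. For genes at an unadjusted p under 0.05, chance could not be excluded in these contrasts. The number of splits with as many was 40 of 100 for VTM_MG against NoVTM_LG (405 genes, highest other 1943), 25 for VTM_MG against NoVTM_MG (650 and 2216) and 23 for VTM_LG against NoVTM_LG (1174 and 2858). It was 21 for VTM_LG against NoVTM_MG (1272 and 2343), 18 for NoVTM_MG against NoVTM_LG (653 and 1716) and 83 for supplementation (412 and 1884). It was 5 for the interaction (1516 and 2142).

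The other gaps are given as values. VTM_MG replicate 4 had 17801 genes detected, against 17279 to 17501 in its group. ENSBTAG00000011803 stood at 20.32 CPM in VTM_LG replicate 1, against 0.2725 to 1.923, and at 0.6735 CPM in VTM_MG replicate 4, against 0.5279 to 0.5903. ENSBTAG00000006320 stood at 58.16 CPM in NoVTM_LG replicate 1, against at most 51.89. ENSBTAG00000007728 stood at 56.64 CPM in VTM_MG replicate 3, against at least 63.8. ENSBTAG00000047175 stood at 33.82 CPM in NoVTM_MG replicate 6, against at most 20.48. ENSBTAG00000047664 stood at 32.2 CPM in NoVTM_MG replicate 8, against at most 26.45.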

How the results depend on the processing

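The fit without VTM_LG replicates 4 and 7, the robust fit, the likelihood ratio test and the first principal component as a covariate were chosen after seeing the data. Of 384 counts of genes under an alternative, 307 were 0 and 2 were above 10. Scaling by relative log expression and the filter of more than 1 CPM in 7 libraries left the count of each contrast as in the main test. The contrasts VTM_LG against NoVTM_LG and VTM_MG against NoVTM_MG and the interaction had 0 genes under each alternative run. The effect of gain was 9 genes in DESeq2, 5 in voom, 6 at an adjusted p of 0.10, 1 with a minimum log2 fold change of 1, and 11 in the likelihood ratio test (10 lower and 1 higher). Supplementation gave 3 genes in DESeq2, 2 in voom, 3 in the likelihood ratio test and 1 without VTM_LG replicates 4 and 7. NoVTM_MG against NoVTM_LG gave 9 in DESeq2, 2 in voom, 2 at an adjusted p of 0.10, 1 without VTM_LG replicates 4 and 7, 2 in the robust fit, 7 in the likelihood ratio test and 1 with the first principal component as a covariate. VTM_LG against NoVTM_MG gave 6 in DESeq2, 1 with only its groups in the fit, 1 without VTM_LG replicates 4 and 7 and 6 in the likelihood ratio test. VTM_MG against NoVTM_LG gave 1 in DESeq2 and 1 in the likelihood ratio test, as did VTM_MG against VTM_LG. The cause of these differences was not tested, except that a looser or stricter threshold changes the count by construction. When each library was left out in turn, the count ranged from 0 to 7 for gain, 0 to 3 for supplementation, 0 to 7 for NoVTM_MG against NoVTM_LG, 0 to 2 for VTM_LG against NoVTM_MG and 0 to 23 for VTM_MG against VTM_LG, where 23 was reached without VTM_LG replicate 8. The highest gain count, 7, and the highest NoVTM_MG against NoVTM_LG count, 7, were reached without NoVTM_LG replicate 3, and the lowest gain count, 0, without VTM_MG replicate 2. Of 1503 fold changes of single genes under an alternative, 0 changed sign, 15 lost the threshold and 62 gained it. These genes were picked for a small p in the same data, and most alternatives left out only 1 library. The lack of sign changes therefore says little. No paired analysis was possible because the replicate numbers are names only. The erythroid covariate and the gene list tests were not run, since no identifier could be matched to a symbol. Depth was not varied, so its limit was not measured apart from the spread. The median SE was 0.158 for the interaction and 0.0789 for supplementation, and 38% of simulated 1.5-fold interactions were recovered among 14147 genes.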

Other observations

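The first tests of shared variation were set before their results were seen, and those against other splits of the libraries after. The 6 genes with an adjusted p under 0.10 for gain, all lower in MG, varied together between fetuses of the same group. After subtraction of group means, the mean pairwise correlation over the 31 libraries was 0.379 (mean Spearman rho 0.348), with 14 of 15 pairs positive. Among 10000 random sets of 6 genes of like expression the 95th percentile was 0.152. These sets were not picked on p, and correlated genes reach a small p together, so that percentile is too low a bar. Where 6 genes were picked by p in the same way under other splits by gain, the median was 0.0708 and the highest 0.485, and 2 of 100 splits reached 0.379, the real one included. Without VTM_LG replicates 4 and 7 the value was 0.385. A candidate explanation is variation between fetuses that these genes share, but the most correlated pair had an r of 0.889, and overlap or shared reads of such a pair could not be checked.

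The 6 genes with the smallest p for supplementation were 4 lower and 2 higher in VTM. In the first test, without signs, their mean pairwise correlation was 0.206, with 6 of 15 pairs positive. The 95th percentile of random sets, which were not picked on p, was 0.136. With each gene signed by its direction, the mean pairwise correlation was 0.387, with 14 of 15 pairs positive. Of 100 splits by supplementation with genes picked and signed in the same way, 1 reached this value, the real one, and the highest of the others was 0.295. The most correlated pair had an r of 0.844, and shared reads could not be checked here either. None of these genes passed the threshold for supplementation in edgeR, where 412 genes had an unadjusted p under 0.05, DESeq2 called 3 and voom 2.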
